A study of Mus musculus with 16 samples.

How the data were processed

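Total RNA was taken from mouse hearts with TRIzol, and libraries were made with the NEBNext Ultra RNA kit, which does not keep the strand, so reads of overlapping genes on opposite strands cannot be told apart. There were 16 libraries in 4 groups of 4, from mice given doxorubicin or saline after NMN or saline. Groups were taken from the labels of the samples. Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 to GRCm38 and counted per gene with HTSeq 0.6.0. The annotation release, the strand setting and any read filters are not given in the sources used here. The deposited tables give raw counts per gene and library for 30884 genes, and FPKM for the same genes. The FPKM values that the authors deposited equal the counts divided by each library's total and a single length per gene, with a largest relative deviation of 9.4e-15. No replicates were pooled. The tables call all 30884 genes protein coding, but of 30789 identifiers matched to GENCODE release M21, whose positions were the same for 98.9%, 18010 are protein coding there. For 18 symbols there were 2 or more identifiers, and genes were handled by identifier.

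Totals ran from 13.9 M to 16.4 M counts per library, so 3 counts stood for 0.183 to 0.215 CPM. Counts were analysed in R 4.3.3 with edgeR 4.0.16. After edgeR's default expression filter 14716 genes were tested, with TMM scaling and a single quasi-likelihood fit over the 4 groups (common dispersion 0.0377, a coefficient of variation of 19.4%). The comparisons were doxorubicin vehicle against sham vehicle, doxorubicin NMN against doxorubicin vehicle, sham NMN against sham vehicle, doxorubicin NMN against sham NMN, their interaction, and the mean doxorubicin effect. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg). Log2 CPM used a prior count of 2. SE is the standard error of the log2 fold. Means carry the SD of 4 libraries.

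Lists of genes, 32 for pathways and 17 for cell types, were tested with camera in limma 3.58.1 on voom values at its preset correlation of 0.01, again with a correlation estimated per list, and with fry. Of their members, 4 were missing from the tables. In 5 lists fewer than 4 members could be tested, and in 1 of these a single member. A list's members were also adjusted over the list alone. The doxorubicin signature score of a library was its mean position, weighted by the mean doxorubicin effect, along the genes called for that effect, scaled from the mean sham to the mean doxorubicin library, and was compared by exact permutation of the labels.

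The comparisons, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took, in each of the 3 main comparisons, the 8 highest and 8 lowest folds among called genes with a mean CPM of at least 5 in the higher group and no overlap between groups, up to 4 members per list with the smallest p, and 25 genes named in every comparison. For doxorubicin NMN against sham NMN and for the interaction it took the 5 smallest p in each direction and the same 25 genes, and where no gene was called, the 5 smallest p. Not every gene the rule allows is reported here.

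Alternatives were RLE and upper-quartile scaling, a CPM filter or no filter, DESeq2 1.42.0, limma-voom with and without library weights, limma-trend on the deposited FPKM with 2 pseudocounts and 2 filters, stricter thresholds, a fit of only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. After the data were seen, a split of the libraries that crosses the groups was added as a term, as subsets and with replicate 3 of doxorubicin NMN left out. The split was drawn at the largest gap in the mean of Scand1, Cox11 and Mrps34. Correlations of folds that share libraries were compared with 20 simulations without an effect.

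The steps were tested on simulated data with 14508 genes tested. A small share of genes was changed, in doxorubicin vehicle alone, with the same spread per gene in all groups. The rates below need not hold for the real comparisons, where up to 7145 of 14716 genes were called. For doxorubicin vehicle against sham vehicle, edgeR found 21.2% of 66 genes changed by 0.5 on the log2 scale, 61.2% of 67 changed by 1 and 92.1% of 63 changed by 2. For the interaction it found 4.55%, 43.3% and 74.6%. In the 2 comparisons where nothing was changed it called 0 genes, with 677 and 672 under an unadjusted p of 0.05. Of 14312 unchanged genes it called 7 in doxorubicin vehicle against sham vehicle, 9 in doxorubicin NMN against doxorubicin vehicle and 2 in the interaction. A score difference made as -2 came out as -1.76 (exact permutation p = 0.0286). A list of changed genes passed camera and a list of unchanged genes did not.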

Results

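Messenger RNA was sequenced from the hearts of male C57BL/6 mice, 8 weeks of age, in 4 groups of 4 libraries. Doxorubicin, an anthracycline chemotherapy drug that blocks topoisomerase II and can injure heart muscle, was injected once at 15 mg/kg, and sham mice received saline instead. Nicotinamide mononucleotide (NMN), a precursor from which cells make the coenzyme NAD, was injected at 500 mg/kg 30 min before doxorubicin, and vehicle mice received saline in its place. Hearts were taken 5 days later. The groups are called sham vehicle, sham NMN, doxorubicin vehicle and doxorubicin NMN. Total counts ran from 13.9 M to 16.4 M per library, with means of 15.8 M ± 0.545 in sham vehicle, 15.0 ± 0.699 in sham NMN, 15.8 ± 0.497 in doxorubicin vehicle and 14.7 ± 0.801 in doxorubicin NMN (SD, n = 4 each). Of 30884 genes in the tables, 14716 had enough counts to be tested. The labels number the replicates and say no more of them, so p-values measure the spread between these samples. No pair of replicates agreed within sampling noise, since chi-square per gene ran from 3.88 to 72.9.

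The libraries separated mainly by doxorubicin without NMN. The first principal component held 55.8% of the variance, with means of 73.0 ± 32.5 in doxorubicin vehicle, -10.2 ± 17.3 in doxorubicin NMN, -29.7 ± 5.19 in sham NMN and -33.1 ± 3.52 in sham vehicle. Mitochondrially encoded transcripts took 26.4% ± 1.06 of all counts in sham vehicle, 26.0% ± 0.885 in sham NMN, 22.9% ± 0.931 in doxorubicin vehicle and 26.0% ± 0.984 in doxorubicin NMN. A split that crosses the groups ran through the libraries, unevenly, with 2 of 4 libraries of each vehicle group and 1 of 4 of each NMN group in its smaller part. Replicates 3 and 4 of sham vehicle, 4 of sham NMN, 3 and 4 of doxorubicin vehicle and 4 of doxorubicin NMN read low in Scand1, Cox11 and Mrps34, 3 genes chosen after their values were seen. These 6 libraries are called the second part, and the other 10 the first part. Doxorubicin vehicle fell into 2 pairs along the split, with chi-square per gene of 13.6 and 5.73 within the parts and 56.2 to 72.9 across them. Inflammatory scores of this group were 1.17 and 1.01 in the first part and 2.07 and 2.08 in the second. Calcium-handling scores did not follow the split, at -0.93 and -0.69 and at -0.87 and -0.83. Means and SD of this group combine both parts. Replicate 3 of doxorubicin NMN lay close to the sham libraries, outside their range in 10 of 49 gene lists, where each doxorubicin vehicle library lay outside it in 38 to 41.

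Doxorubicin vehicle against sham vehicle gave the effect of the drug on the heart. Most calcium-cycling and ion channel genes fell, and most antioxidant, p53 target, autophagy, ribosomal protein and neutrophil genes rose, with the count for each list given in turn. Myh6, the main myosin heavy chain of the adult mouse ventricle, fell from 29389 ± 3059.8 to 3633 ± 1266 CPM (SD, n = 4 each, log2 fold -3.02, SE 0.26), and Myh7, its fetal counterpart, rose from 327 ± 150.1 to 10979 ± 3644 CPM (log2 fold 5.07, SE 0.95). Cdkn1a, the cell cycle inhibitor p21, rose from 28.8 ± 9.26 to 201 ± 27.5 CPM (log2 fold 2.80, SE 0.35), and Hmox1, which breaks down haem, from 7.16 ± 1.31 to 301 ± 242 CPM (log2 fold 5.39, SE 0.67). Hmox1 differed along the split of the libraries. It was at 113 and 71.3 CPM in replicates 1 and 2 of doxorubicin vehicle and 525 and 494 in 3 and 4. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 7.7e-07 for Myh6, 7.8e-04 for Myh7, 3.1e-05 for Cdkn1a and 4.1e-05 for Hmox1. On GRCm38 the files place Myh6 (ENSMUSG00000040752.16) on chromosome 14 from 54941921 to 54966927, Myh7 (ENSMUSG00000053093.16) on chromosome 14 from 54970684 to 54994626, Cdkn1a (ENSMUSG00000023067.14) on chromosome 17 from 29090976 to 29100727 and Hmox1 (ENSMUSG00000005413.8) on chromosome 8 from 75093621 to 75100589.

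Among the muscle genes, 0 of 14 calcium-handling genes rose, 12 fell and 2 did not pass (0 and 12 adjusted over the list alone). Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell from 1092 ± 86.2 to 386 ± 12.5 CPM (log2 fold -1.50, SE 0.10), Ryr2, the calcium release channel, had log2 fold -1.28, SE 0.16, and Atp2a2, the calcium pump SERCA2, log2 fold -0.86, SE 0.12. Of the ion channel and conduction genes, 0 of 17 rose, 11 fell and 6 did not pass (0 and 11 adjusted over the list alone). Hcn4, a pacemaker channel, had log2 fold -3.45, SE 0.33, and Kcnq1, a repolarising potassium channel, log2 fold -1.17, SE 0.11. Atrial marker scores were low in doxorubicin vehicle as well (-2.32 to -1.47). Replicate 3 of sham vehicle had an atrial score of -1.86 and a channel score of 0.01. How far the atrial share of a sample moved single channel genes was not tested. In the cardiomyocyte marker list, 2 of 12 rose, 8 fell and 2 did not pass (3 and 8 adjusted over the list alone). Sarcomere genes went both ways, since 4 of 18 rose, 8 fell and 6 did not pass (4 and 8 adjusted over the list alone). The cardiac stress genes were mixed too, with a median of -0.41, a mean of 0.65 and a test that pointed up, and 4 of 9 rose, 3 fell and 2 did not pass (4 and 3 adjusted over the list alone). Ankrd1, a stretch-responsive nuclear protein (log2 fold 3.27, SE 0.38), and Ccn2, a matrix-associated growth factor (log2 fold 3.64, SE 0.39), rose. Nppa and Nppb, the natriuretic peptides, did not pass (log2 folds -0.79 and -0.41), although Nppa was called without replicate 3 of sham vehicle (-1.04). By camera, calcium handling, ion channels and cardiomyocyte markers passed (adjusted p = 1.6e-06 to 9.8e-04) and sarcomere (0.0645) and cardiac stress genes did not, and adjusted p = 0.283 to 0.569 with an estimated correlation, where none passed. The files place Hrc (ENSMUSG00000038239.11) on chromosome 7 from 45335290 to 45338974 and Atp2a2 (ENSMUSG00000029467.15) on chromosome 5 from 122453513 to 122502225.

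Most stress genes rose. Of the p53 target genes, 14 of 22 rose, 1 fell and 7 did not pass (14 and 1 adjusted over the list alone). Ephx1, an epoxide hydrolase (log2 fold 2.04, SE 0.18), and Fas, a death receptor (log2 fold 1.65, SE 0.21), rose, while Ccng1, a cyclin that p53 induces, fell (log2 fold -1.80, SE 0.18), and Mdm2, which degrades p53, stayed at 64.8 ± 3.55 CPM against 64.1 ± 1.11. In the antioxidant and NRF2 list, 22 of 29 rose, 3 fell and 4 did not pass (22 and 3 adjusted over the list alone). Nqo1, a quinone reductase (log2 fold 2.95, SE 0.27), Cat, catalase (log2 fold 1.63, SE 0.13), and Mt1, a metallothionein (log2 fold 3.06, SE 0.29), were among them. For iron and ferroptosis genes, 10 of 20 rose, 4 fell and 6 did not pass (10 and 5 adjusted over the list alone), and Fth1, the ferritin heavy chain, rose (log2 fold 1.88, SE 0.19). Among autophagy, lysosome and atrophy genes, 18 of 25 rose, 2 fell and 5 did not pass (18 and 2 adjusted over the list alone), led by Gabarapl1 (log2 fold 2.13, SE 0.13) and the cargo receptor Sqstm1 (log2 fold 2.78, SE 0.30). Unfolded protein and integrated stress response genes followed, as 11 of 24 rose, 2 fell and 11 did not pass (11 and 2 adjusted over the list alone). Immediate early genes, such as the transcription factor Junb (log2 fold 3.41, SE 0.30), gave 10 higher, 0 lower and 5 not passing of 15 (10 and 0 adjusted over the list alone). The glucocorticoid-responsive list, which shares Mt1 and Lcn2 with others, gave 13 higher, 0 lower and 2 not passing of 15 (14 and 0 adjusted over the list alone). By camera, p53 targets, antioxidant, autophagy, unfolded protein response, immediate early and glucocorticoid lists passed (adjusted p = 2.3e-07 to 0.0268) and iron genes did not (0.0645), and adjusted p = 0.283 to 0.299 with an estimated correlation, where none passed. The files place Nqo1 (ENSMUSG00000003849.8) on chromosome 8 from 107388225 to 107403206, Cat (ENSMUSG00000027187.10) on chromosome 2 from 103453849 to 103485160 and Gabarapl1 (ENSMUSG00000030161.8) on chromosome 6 from 129533160 to 129542346.

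Genes of protein synthesis rose nearly throughout. Of the ribosomal protein genes, 28 of 30 rose, 0 fell and 2 did not pass (28 and 0 adjusted over the list alone), for example Rpl3 (log2 fold 1.30, SE 0.16) and Rps18 (log2 fold 0.93, SE 0.11). Ribosome biogenesis and MYC target genes gave 15 higher, 0 lower and 4 not passing of 19 (15 and 0 adjusted over the list alone). Myc itself, a growth-promoting transcription factor, rose from 2.48 ± 0.956 to 37.0 ± 9.68 CPM (log2 fold 3.89, SE 0.33), and the nucleolar protein gene Gnl3 had log2 fold 1.78, SE 0.14. By camera, ribosomal proteins and ribosome biogenesis passed (adjusted p = 2.8e-12 to 2.3e-07), and adjusted p = 0.283 with an estimated correlation, where none passed.

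Among genes of energy metabolism, more fell than rose in the mitochondrial, TCA cycle and glycolysis lists. Among nuclear genes of oxidative phosphorylation, 1 of 43 rose, 22 fell and 20 did not pass (1 and 22 adjusted over the list alone), with Ndufs8 of complex I at log2 fold -1.13, SE 0.13. Mitochondrially encoded genes gave 0 higher, 4 lower and 8 not passing of 12 (0 and 4 adjusted over the list alone), and mitochondrial biogenesis genes 2 higher, 11 lower and 6 not passing of 19 (2 and 11 adjusted over the list alone), with the muscle regulator Perm1 at log2 fold -1.50, SE 0.23. Of the TCA cycle genes, 1 of 20 rose, 13 fell and 6 did not pass (1 and 13 adjusted over the list alone), with Idh3a at log2 fold -0.96, SE 0.11. Glycolysis and glucose uptake genes gave 2 higher, 11 lower and 7 not passing of 20 (2 and 11 adjusted over the list alone); the insulin-responsive glucose transporter Slc2a4 (log2 fold -1.43, SE 0.11) and hexokinase Hk2 (log2 fold -1.61, SE 0.14) fell. PPAR alpha targets went the other way, as 7 of 15 rose, 0 fell and 8 did not pass (8 and 0 adjusted over the list alone), with the thioesterase Acot1 (log2 fold 3.25, SE 0.42) higher. The mean score of this list was high only in replicates 1 and 2 of doxorubicin vehicle (2.09 and 2.15), both of the first part, while replicates 3 and 4 (-0.02 and -0.06) lay within the sham vehicle range of -0.22 to 0.18. Genes of NAD synthesis and use did not move as a group, with a median of 0.11, a mean of 0.16 and a test that pointed down, and 7 of 27 rose, 9 fell and 11 did not pass (8 and 10 adjusted over the list alone). Within it Sirt3, the mitochondrial NAD-dependent deacetylase, fell from 31.7 ± 2.94 to 13.9 ± 5.10 CPM (log2 fold -1.19, SE 0.19), Parp1, which uses NAD in DNA repair, fell (log2 fold -0.72, SE 0.10), as did Nmnat1 (log2 fold -0.82, SE 0.18), while Nampt, which makes NMN in the cell (log2 fold 0.55, SE 0.17), Sirt1 (log2 fold 0.99, SE 0.19) and Aox1, an aldehyde oxidase that also oxidises nicotinamide metabolites (log2 fold 2.64, SE 0.30), rose. Nmrk2, a muscle nicotinamide riboside kinase, did not pass (log2 fold 0.71, SE 0.31), but was called without replicate 1 of sham vehicle (1.03). Fatty acid oxidation genes gave 6 higher, 4 lower and 12 not passing of 22 (6 and 4 adjusted over the list alone). By camera, oxidative phosphorylation, mitochondrially encoded, mitochondrial biogenesis, TCA cycle, glycolysis and PPAR alpha lists passed (adjusted p = 4.1e-04 to 0.0333) and fatty acid oxidation and NAD genes did not (0.467 to 0.941), and adjusted p = 0.283 to 0.934 with an estimated correlation, where none passed. The files place Sirt3 (ENSMUSG00000025486.17) on chromosome 7 from 140863666 to 140882309 and Slc2a4 (ENSMUSG00000018566.14) on chromosome 11 from 69942539 to 69948188.

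Inflammatory and blood cell genes also differed. Inflammatory mediators gave 14 higher, 3 lower and 6 not passing of 23 (14 and 3 adjusted over the list alone). Lcn2, which binds bacterial iron carriers (log2 fold 4.46, SE 0.41), the protease inhibitor Serpina3n (log2 fold 5.84, SE 0.59) and the neutrophil attractant Cxcl1 (log2 fold 3.52, SE 0.46) rose. Saa3, an acute-phase protein, rose from 0 counts in all 4 sham vehicle libraries to 15.0 ± 14.2 CPM, where 3 counts would stand for 0.183 to 0.215 CPM, a floor that covers counting error only. Among neutrophil markers, 9 of 10 rose, 0 fell and 1 did not pass (10 and 0 adjusted over the list alone), with S100a8 from 0.369 ± 0.302 to 12.4 ± 6.41 CPM and Cxcr2, a chemokine receptor, from 0.142 ± 0.115 to 2.36 ± 0.730 CPM. Antigen presentation by MHC class II went down, as 0 of 7 rose, 7 fell and 0 did not pass (0 and 7 adjusted over the list alone), with the invariant chain Cd74 at log2 fold -1.77, SE 0.32 and H2-Aa at log2 fold -1.92, SE 0.35. Markers of B cells, which carry MHC class II, were lower too, with a mean score of -1.78 in doxorubicin vehicle, and 0 of 3 rose, 2 fell and 1 did not pass (0 and 2 adjusted over the list alone), with the antibody chain gene Ighm at log2 fold -3.46, SE 0.38. Ager, a pattern receptor and the 1 gene of the lung list that could be tested, rose (log2 fold 2.65, SE 0.50), and had log2 fold -2.04, SE 0.48 in doxorubicin NMN against doxorubicin vehicle. Erythroid genes fell to near 0, as 0 of 6 rose, 5 fell and 1 did not pass (0 and 5 adjusted over the list alone). Hbb-bs, a beta globin, fell from 239 ± 49.2 to 0.386 ± 0.467 CPM, and Alas2, the enzyme that starts haem synthesis in red cells, from 13.6 ± 3.70 to 0.189 ± 0.0821 CPM. By camera, inflammatory, neutrophil, MHC class II and erythroid lists passed (adjusted p = 1.2e-04 to 0.00252) and B cell and lung did not (0.0703 to 0.283), and adjusted p = 0.283 to 0.432 with an estimated correlation, where none passed. Globin genes share near-identical copies, as do Mt1 and Mt2 and the Saa genes, and Myh6 resembles Myh7, so how reads were divided among them is uncertain. The files place Lcn2 (ENSMUSG00000026822.14) on chromosome 2 from 32384633 to 32388252, Cd74 (ENSMUSG00000024610.15) on chromosome 18 from 60803848 to 60812652 and Hbb-bs (ENSMUSG00000052305.6) on chromosome 7 from 103826534 to 103828096.

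Over all genes, 7145 of 14716 were called, 3635 higher and 3510 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), and 2629 of them changed over 2-fold. With upper-quartile scaling 3064 were higher and 4058 lower (43.0% higher). The count was 7730 with the split as a term, 4128 within the first part and 9586 within the second. Camera called 23 of 49 lists, 11 up and 12 down, and none with an estimated correlation, where the lowest adjusted p was 0.283. Directions of the thymocyte, platelet and mesothelial lists depended on the scaling.

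**Figure D1:**
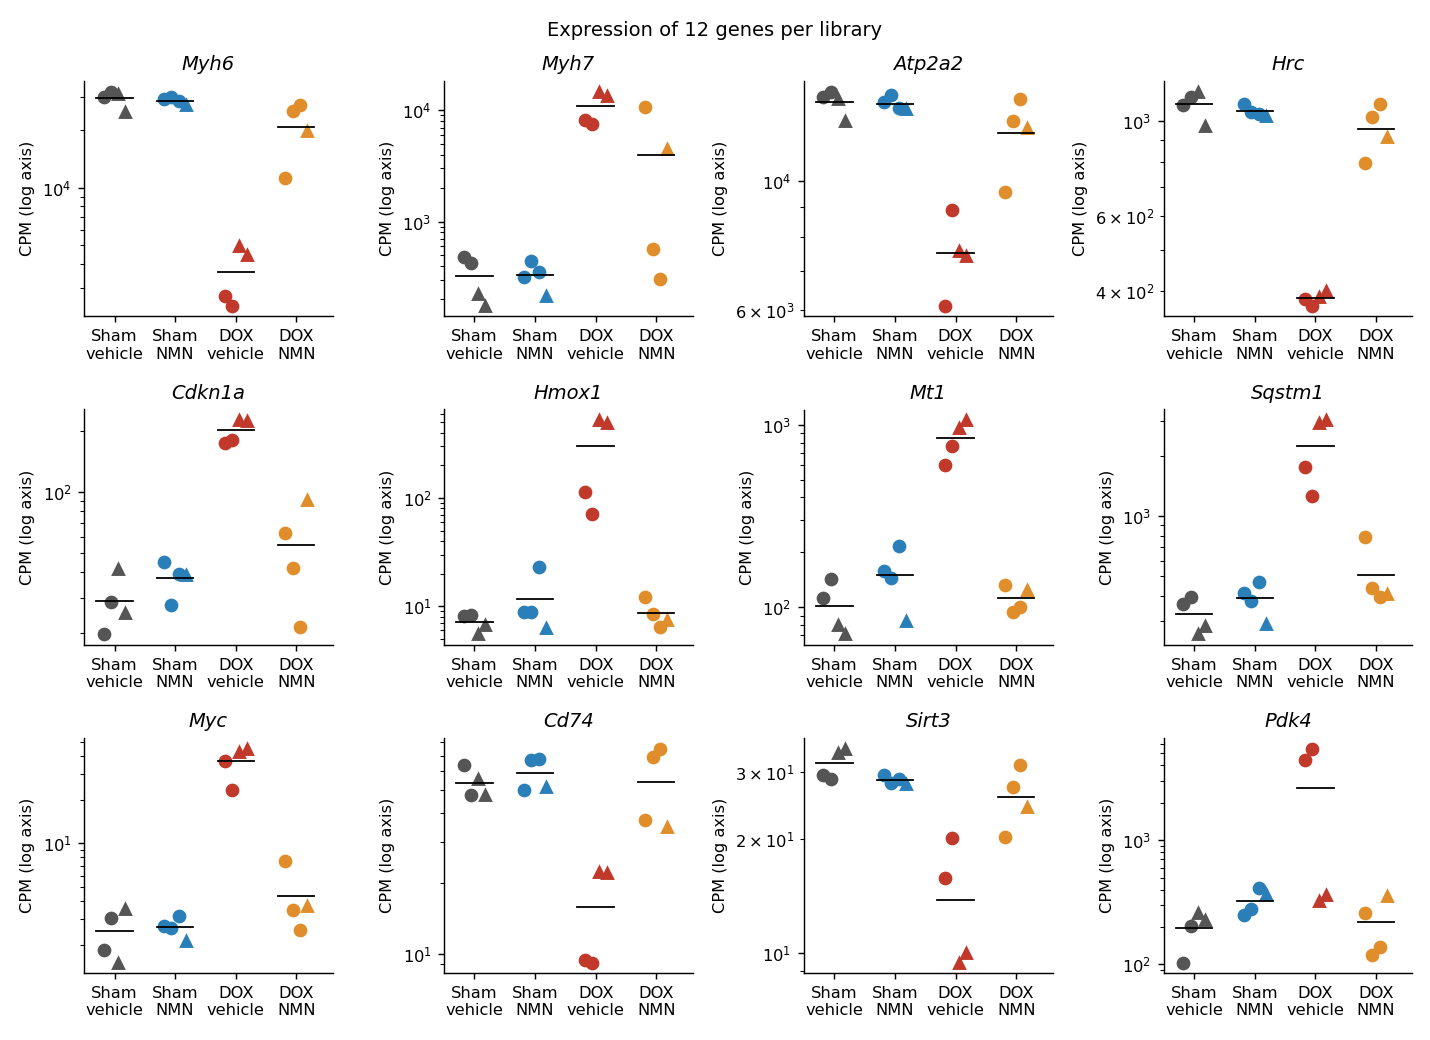
CPM on a log axis for 12 genes in the 4 groups, with 1 symbol per library, circles for the first part of the split, triangles for the second, and a line at each mean. Myh6 averages 3633 CPM in doxorubicin vehicle and 20858 in doxorubicin NMN, and Hmox1 301 and 8.63. Within doxorubicin vehicle Hmox1 ranges from 71.3 to 525 CPM, lower in the first part of the split.

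The comparison the series is about set doxorubicin NMN against doxorubicin vehicle. Most of the doxorubicin-affected groups moved back towards their sham levels in the NMN mice. Myh6 rose from 3633 ± 1266 to 20858 ± 7139 CPM (SD, n = 4 each, log2 fold 2.52, SE 0.26), against 29389 ± 3059.8 in sham vehicle. Hmox1 fell from 301 ± 242 to 8.63 ± 2.49 CPM (log2 fold -5.12, SE 0.66) and Cdkn1a from 201 ± 27.5 to 54.3 ± 29.8 CPM (log2 fold -1.89, SE 0.34). For Hmox1 the size of the fall depends on the part of the split, with libraries at 71.3 to 525 CPM in doxorubicin vehicle. Those of doxorubicin NMN lay at 6.43 to 12.2 CPM. Adjusted p was 8.2e-06, 1.3e-04 and 8.7e-04 for these 3 genes (edgeR quasi-likelihood, Benjamini-Hochberg). Myh7 did not pass, at 4000.2 ± 4834 CPM (log2 fold -1.46, SE 0.82), although it was called by limma-voom (-2.64), by limma-trend on log2(FPKM + 1) (-2.61) and without replicate 1 of doxorubicin NMN (-2.62).

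Most calcium-handling and channel genes rose. In the calcium-handling list, 10 of 14 rose, 0 fell and 4 did not pass (10 and 0 adjusted over the list alone), with Hrc at 958 ± 129.7 CPM (log2 fold 1.31, SE 0.10) and Atp2a2 at 12085 ± 1791 CPM (log2 fold 0.69, SE 0.12). Ion channel and conduction genes gave 12 higher, 0 lower and 5 not passing of 17 (13 and 0 adjusted over the list alone), with Hcn4 (log2 fold 2.71, SE 0.33) and Kcnq1 (log2 fold 0.96, SE 0.11) higher. Of the cardiomyocyte markers, 8 of 12 rose, 2 fell and 2 did not pass (8 and 2 adjusted over the list alone), including the ventricular myosin light chain Myl2 (log2 fold 0.98, SE 0.14). Sarcomere genes were split again, with 8 higher, 3 lower and 7 not passing of 18 (8 and 4 adjusted over the list alone). Among cardiac stress genes the median was 0.66, the mean -0.43 and the test pointed down, with 1 higher, 3 lower and 5 not passing of 9 (1 and 3 adjusted over the list alone), where Ankrd1 (log2 fold -2.53, SE 0.37) and Ccn2 (log2 fold -2.75, SE 0.37) fell. By camera, calcium handling, ion channels and cardiomyocyte markers passed (adjusted p = 3.5e-06 to 0.00185) and sarcomere and cardiac stress did not (0.0529 to 0.331), and adjusted p = 0.298 to 0.513 with an estimated correlation, where none passed.

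Many stress genes fell with NMN. p53 targets gave 1 higher, 10 lower and 11 not passing of 22 (1 and 10 adjusted over the list alone), with Ephx1 (log2 fold -0.97, SE 0.17) and Fas (log2 fold -1.10, SE 0.20) down and Ccng1 up (log2 fold 1.39, SE 0.18). In the antioxidant and NRF2 list, 3 of 29 rose, 20 fell and 6 did not pass (3 and 21 adjusted over the list alone), among them Nqo1 (log2 fold -2.12, SE 0.26), Cat (log2 fold -1.46, SE 0.13) and Mt1 (log2 fold -2.91, SE 0.29). Iron and ferroptosis genes gave 3 higher, 9 lower and 8 not passing of 20 (4 and 9 adjusted over the list alone), with Fth1 at log2 fold -1.30, SE 0.19. For autophagy, lysosome and atrophy genes, 2 of 25 rose, 11 fell and 12 did not pass (2 and 15 adjusted over the list alone), with Gabarapl1 (log2 fold -1.66, SE 0.13) and Sqstm1 (log2 fold -2.14, SE 0.29) down. The unfolded protein and integrated stress response list gave 3 higher, 8 lower and 13 not passing of 24 (3 and 8 adjusted over the list alone). Immediate early genes gave 0 higher, 8 lower and 7 not passing of 15 (0 and 10 adjusted over the list alone), and Junb fell (log2 fold -2.88, SE 0.29). Among glucocorticoid-responsive genes, 0 of 15 rose, 8 fell and 7 did not pass (0 and 9 adjusted over the list alone), with the steroid receptor cochaperone Fkbp5 at log2 fold -1.57, SE 0.40. Ribosomal protein genes gave 0 higher, 28 lower and 2 not passing of 30 (0 and 28 adjusted over the list alone), with Rpl3 at log2 fold -0.88, SE 0.16 and Rps18 at log2 fold -0.68, SE 0.11, and ribosome biogenesis and MYC target genes 0 higher, 15 lower and 4 not passing of 19 (0 and 16 adjusted over the list alone), with Myc from 37.0 ± 9.68 to 4.31 ± 2.23 CPM (log2 fold -3.10, SE 0.31). By camera, p53 targets, antioxidant, iron, autophagy, immediate early, glucocorticoid, ribosomal protein and ribosome biogenesis lists passed (adjusted p = 2.2e-11 to 0.0353) and the unfolded protein response did not (0.152), and adjusted p = 0.298 to 0.443 with an estimated correlation, where none passed.

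Mitochondrial genes that were called mostly rose. Of the nuclear genes of oxidative phosphorylation, 14 of 43 rose, 1 fell and 28 did not pass (15 and 1 adjusted over the list alone), with Ndufs8 at log2 fold 0.74, SE 0.13. Mitochondrially encoded genes gave 4 higher, 0 lower and 8 not passing of 12 (4 and 0 adjusted over the list alone). Mitochondrial biogenesis genes gave 8 higher, 1 lower and 10 not passing of 19 (8 and 1 adjusted over the list alone), with Perm1 at log2 fold 1.54, SE 0.23. TCA cycle genes gave 9 higher, 1 lower and 10 not passing of 20 (9 and 1 adjusted over the list alone), with Idh3a at log2 fold 0.60, SE 0.11. In glycolysis and glucose uptake, 10 of 20 rose, 1 fell and 9 did not pass (12 and 2 adjusted over the list alone), where Slc2a4 (log2 fold 1.45, SE 0.11) and Hk2 (log2 fold 1.47, SE 0.14) returned to 419 ± 32.0 and 345 ± 40.3 CPM. PPAR alpha targets fell, as 0 of 15 rose, 9 fell and 6 did not pass (0 and 9 adjusted over the list alone), with Acot1 (log2 fold -3.45, SE 0.43) down. Fatty acid oxidation genes gave 1 higher, 8 lower and 13 not passing of 22 (1 and 8 adjusted over the list alone). In this list and that of the PPAR alpha targets only replicates 1 and 2 of doxorubicin vehicle were high, and for fatty acid oxidation replicates 3 and 4 (-0.20 and -0.18) lay below the doxorubicin NMN mean of -0.15. The NAD list showed no common direction, with a median of -0.12, a test that pointed up and 10 of 27 rose, 4 fell and 13 did not pass (10 and 8 adjusted over the list alone). Sirt3 rose to 25.8 ± 4.66 CPM (log2 fold 0.89, SE 0.19) and Parp1 to 53.8 ± 4.88 CPM (log2 fold 0.47, SE 0.10), and Aox1 fell (log2 fold -2.08, SE 0.30). Sirt1 fell (log2 fold -0.62, SE 0.19) and Nmnat1 rose (log2 fold 0.55, SE 0.18), but each lost its call without replicate 3 or 4 of doxorubicin vehicle, or 2 or 3 of doxorubicin NMN (Sirt1 -0.47 to -0.54, Nmnat1 0.43 to 0.49). Nampt (log2 fold -0.14, SE 0.17) and Nmrk2 (log2 fold -0.22, SE 0.31) did not pass. By camera, oxidative phosphorylation, mitochondrially encoded, mitochondrial biogenesis, TCA cycle, glycolysis, PPAR alpha and fatty acid oxidation lists passed (adjusted p = 6.6e-04 to 0.0127) and NAD genes did not (0.906), and adjusted p = 0.298 to 0.936 with an estimated correlation, where none passed.

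Inflammatory mediators gave 2 higher, 14 lower and 7 not passing of 23 (3 and 15 adjusted over the list alone), with Lcn2 (log2 fold -4.75, SE 0.42), Serpina3n (log2 fold -4.62, SE 0.55) and Cxcl1 (log2 fold -2.95, SE 0.44) down. Of the neutrophil markers, 0 of 10 rose, 9 fell and 1 did not pass (0 and 9 adjusted over the list alone), and S100a8 fell to 1.14 ± 0.932 CPM. MHC class II genes rose, as 7 of 7 rose, 0 fell and 0 did not pass (7 and 0 adjusted over the list alone), with Cd74 (log2 fold 1.78, SE 0.32) and H2-Aa (log2 fold 1.96, SE 0.35). The B cell score went from -1.78 to -0.34 beside them, and Ighm rose (log2 fold 2.93, SE 0.38). Interferon response genes gave 8 higher, 0 lower and 21 not passing of 29 (7 and 0 adjusted over the list alone), including the guanylate-binding proteins Gbp2 (log2 fold 1.04, SE 0.13) and Gbp3 (log2 fold 1.33, SE 0.20), both above their sham vehicle means of 14.3 ± 2.26 and 14.4 ± 3.08 CPM, at 17.2 ± 2.11 and 19.1 ± 3.67 CPM. By camera, inflammatory, neutrophil, MHC class II and interferon lists passed (adjusted p = 3.3e-05 to 0.0127) and B cell markers did not (0.0858), and adjusted p = 0.298 to 0.536 with an estimated correlation, where none passed. Erythroid genes were high in a single library. Hbb-bs was at 174 CPM in replicate 3 of doxorubicin NMN, with 2411 counts there and 38, 0 and 7 in replicates 1, 2 and 4. Without that replicate its log2 fold of 6.82 became 1.37 and was no longer called. Beyond the lists, the higher genes with the largest folds included Apln, a peptide that acts on heart and vessels (log2 fold 5.05, SE 0.67), the membrane proteins Lrrc15 (log2 fold 4.26, SE 0.38) and Mdga1 (log2 fold 4.19, SE 0.36), and Cyp1a1, a drug-metabolising enzyme (log2 fold 4.57, SE 0.97). Apln was at 15.5 ± 6.49 CPM in sham vehicle, 0.239 ± 0.0617 in doxorubicin vehicle and 8.20 ± 5.79 in doxorubicin NMN. Cyp1a1 was at 2.98 ± 1.77 CPM in sham vehicle and 1.23 ± 0.602 in doxorubicin vehicle. In replicates 1 to 4 of doxorubicin NMN it was at 3.38, 85.2, 17.1 and 11.2 CPM, so its mean passed the sham level and rested mostly on replicate 2. The files place Apln (ENSMUSG00000037010.7) on chromosome X from 48025146 to 48034853 and Lrrc15 (ENSMUSG00000052316.9) on chromosome 16 from 30269302 to 30283256.

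Over all genes, 5306 were called, 2561 higher and 2745 lower (edgeR quasi-likelihood, Benjamini-Hochberg), and with upper-quartile scaling 3036 higher and 2266 lower (57.3% higher). The count was 5397 with the split as a term, 3201 within the first part, 6684 within the second, 3936 without replicate 3 of doxorubicin NMN, and 4359 without it and with the split as a term. Camera called 23 lists, 11 up and 12 down, none with an estimated correlation (lowest adjusted p = 0.298). The DNA repair, T and NK cell, thymocyte and platelet lists changed direction with the scaling.

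Since both comparisons use the doxorubicin vehicle libraries, chance alone makes their folds run opposite. Across the 14716 genes, which are not independent replicates, the folds correlated at -0.93, against -0.50 in simulations with no effect, and their covariance was -0.598 against -0.0374, a difference of -0.56. The simulations gave the 4 groups the same spread per gene. Doxorubicin vehicle libraries varied more than sham vehicle (SD 32.5 and 3.52 on the first principal component), so the simulated covariance may be too small. With 2 doxorubicin vehicle libraries used in each comparison, the correlation was -0.88 to -0.68 and the covariance -0.582 to -0.451. Genes then called in both were higher with doxorubicin and lower with NMN in 1063 to 1750 cases, where lists without a link would share 295 to 619, and lower and then higher in 1110 to 1768, against 243 to 643. Over all genes, 73.7% to 85.5% had opposite signs.

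A doxorubicin signature score placed each library on the mean doxorubicin effect over NMN and vehicle mice, with the mean sham library at 0 and the mean doxorubicin library at 1. It used 5817 genes called for that mean effect, 2933 higher and 2884 lower. Scores averaged -0.03 ± 0.07 in sham vehicle, 0.03 ± 0.09 in sham NMN, 1.56 ± 0.36 in doxorubicin vehicle and 0.44 ± 0.27 in doxorubicin NMN (SD, n = 4 each). Doxorubicin NMN minus doxorubicin vehicle was -1.11 (exact two-sided permutation p = 0.0286, the smallest that 70 assignments can give, not adjusted for other comparisons), and its 4 libraries, at 0.69, 0.31, 0.13 and 0.65, all lay below the 4 of doxorubicin vehicle, at 1.35, 1.15, 1.84 and 1.88. With the split removed the difference was -1.07. Permuting within the parts gave p = 0.0333 (exact, the smallest of 30 assignments). It was -0.88 within the first part and -1.21 within the second, where exact permutation p could not fall under 0.10 and 0.333. The sham groups differed by 0.06 (exact permutation p = 0.343), with 0.10 when the split was removed and 0.04 within the first part.

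**Figure D2:**
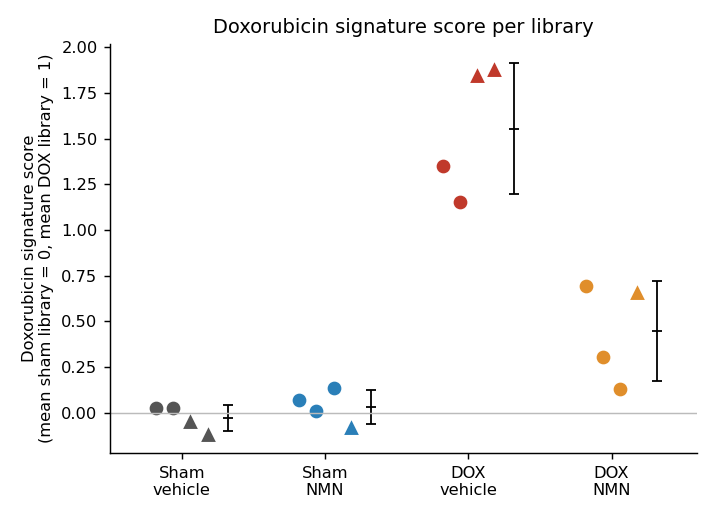
Doxorubicin signature score of each library (vertical axis, 0 for the mean sham library and 1 for the mean doxorubicin library) in the 4 groups, with circles for the first part of the split, triangles for the second, and mean ± SD. Doxorubicin NMN libraries lie at 0.13 to 0.69, below the doxorubicin vehicle libraries at 1.15 to 1.88.

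Doxorubicin NMN against sham NMN gave the drug effect in mice that had NMN. By edgeR no gene was called. Camera called 11 lists at its preset correlation and 0 with an estimated one. Among the 11, p53 target, autophagy and calcium-handling genes leaned in the direction they took with doxorubicin alone. Not all did so, since the interferon list rose here and had a mean score of -0.00395 in doxorubicin vehicle. The mean p53 target score was 0.37 against 0.08 in sham NMN, and that of calcium handling -0.23 against -0.02. Cdkn1a was at 54.3 ± 29.8 CPM against 37.6 ± 7.22 in sham NMN (log2 fold 0.53, SE 0.33, SD, n = 4 each), Hmox1 at 8.63 ± 2.49 against 11.7 ± 7.56 (log2 fold -0.43, SE 0.61) and Myh6 at 20858 ± 7139 against 28606 ± 1158 (log2 fold -0.46, SE 0.24), none of them called. Ephx1, at 73.8 ± 19.5 against 38.5 ± 3.70 CPM (log2 fold 0.94, SE 0.18), and Htatip2 (log2 fold 0.71, SE 0.15) had the smallest p among higher genes, and the somatostatin receptor Sstr3 (log2 fold -0.96, SE 0.22) and Epha4 (log2 fold -0.48, SE 0.12) among lower genes. Each had adjusted p = 0.407 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ephx1 was called without replicate 3 of doxorubicin NMN (1.11). Myh7 was at 4000.2 ± 4834 CPM against 332 ± 95.2 without passing (log2 fold 3.59, SE 0.89), and DESeq2 called it, Ephx1, Htatip2 and Sstr3. The files place Ephx1 (ENSMUSG00000038776.13) on chromosome 1 from 180976210 to 181020904 and Sstr3 (ENSMUSG00000044933.3) on chromosome 15 from 78537008 to 78544685.

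Of the lists, camera called 11, and fry only the erythroid list (adjusted p = 0.0173). With an estimated correlation none was called, and the lowest adjusted p was 0.158. Pointing up were ribosomal proteins (median 0.30, 0 of 30 genes called and 5 higher adjusted over the list alone, camera adjusted p = 5.3e-16, adjusted p = 0.533 with an estimated correlation), the interferon response (0.39, 0 of 29 and 6, camera adjusted p = 3.9e-10, adjusted p = 0.539 with an estimated correlation) and p53 targets (0.26, 0 of 22 and 1, camera adjusted p = 0.00166, adjusted p = 0.425 with an estimated correlation), with autophagy (0.13), ribosome biogenesis (0.12) and neutrophil genes (1.18). The neutrophil scores were 1.53 in replicate 1 of doxorubicin NMN and 0.20, 0.38 and 0.27 in replicates 2, 3 and 4, and replicate 2 of sham NMN had 1.24. Pointing down were calcium handling (-0.17, 0 of 14 called and 3 lower adjusted over the list alone, camera adjusted p = 9.6e-05, adjusted p = 0.533 with an estimated correlation), extracellular matrix (-0.60, 0 of 33 and 1, camera adjusted p = 1.6e-09, adjusted p = 0.558 with an estimated correlation), fibroblast (-0.26), macrophage (-0.25) and erythroid genes (-1.75, camera adjusted p = 1.6e-10, adjusted p = 0.158 with an estimated correlation). The erythroid scores were -5.28, -6.50 and -5.83 in replicates 1, 2 and 4 of doxorubicin NMN and -0.47 in replicate 3, which drew the folds towards 0. The thymocyte list changed direction with the scaling.

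Over all genes, edgeR's quasi-likelihood test called 0, with 1205 at unadjusted p under 0.05 against 735.8 expected by chance. DESeq2 called 10, limma-voom 0, limma-voom with library weights 1, limma-trend on FPKM 0 with either pseudocount, and limma-trend over all genes 4. Without replicate 3 of doxorubicin NMN, 21 genes were called (8 higher), and 45 (25 higher) without it and with the split as a term. The count was 0 with the split as a term, 0 within the first part and 1911 within the second, where each group held 1 library assumed to vary like the others. The signature score was higher by 0.41, on genes that were called with these same libraries included, so no p is given. This comparison shares no library with doxorubicin vehicle against sham vehicle. Their folds correlated at 0.49 across genes (0.00 in simulations with no effect), and 5525 of the 7145 doxorubicin genes (77.3%) had the same sign in both, with a median ratio of 0.17.

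Sham NMN against sham vehicle gave the effect of NMN alone, 5 days after its injection. By edgeR no gene was called. Means in sham NMN and sham vehicle were close for Myh6, at 28606 ± 1158 and 29389 ± 3059.8 CPM (SD, n = 4 each), and for Sirt3, at 28.6 ± 0.703 and 31.7 ± 2.94. Other doxorubicin-affected genes had means further apart without being called. Hmox1 was at 11.7 ± 7.56 and 7.16 ± 1.31 CPM, Cdkn1a at 37.6 ± 7.22 and 28.8 ± 9.26, and Mt1 at 151 ± 54.2 and 102 ± 32.9. Pdk4 was at 326 ± 74.9 and 197 ± 66.8 CPM, and Hbb-bs at 142 ± 9.27 and 239 ± 49.2. NAD genes did not pass, for example Nampt (log2 fold 0.19, SE 0.17), the NAD-consuming enzyme Cd38 (log2 fold -0.47, SE 0.19) and Nmrk2 (log2 fold -0.73, SE 0.32). The smallest p-values belonged to the ubiquitin ligase Hecw2 (log2 fold 0.72, SE 0.15), Bahcc1 (log2 fold -0.55, SE 0.14), Gm6852 (log2 fold 1.01, SE 0.27), Bex1 (log2 fold -2.21, SE 0.59) and Arfip1 (log2 fold -0.91, SE 0.25), all with adjusted p = 1.0 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The glucocorticoid-responsive list pointed up by camera (median 0.43, camera adjusted p = 3.8e-09, adjusted p = 0.523 with an estimated correlation), with 0 of 15 genes called and 1 adjusted over the list alone. Its Zbtb16, a transcription factor (log2 fold 1.31, SE 0.35), and Fkbp5 (log2 fold 1.08, SE 0.40) had large folds without passing. The scores of this list followed the split, which is uneven between the sham groups. In the second part they were -0.26 and -0.49 (replicates 3 and 4 of sham vehicle) and -0.09 (replicate 4 of sham NMN). Sham libraries of the first part had 0.12 to 0.98. With the split as a term camera still called this list. Pointing down by camera were erythroid (-0.79, camera adjusted p = 3.3e-04, adjusted p = 0.696 with an estimated correlation), T and NK cell (-1.07, 2 genes tested, camera adjusted p = 0.0162, adjusted p = 0.523 with an estimated correlation), oxidative phosphorylation (-0.13, camera adjusted p = 1.5e-05, adjusted p = 0.977 with an estimated correlation), ribosomal protein (-0.08, camera adjusted p = 0.00269, adjusted p = 0.977 with an estimated correlation) and fatty acid oxidation genes (-0.08, camera adjusted p = 0.0246, adjusted p = 0.977 with an estimated correlation), with 0 genes called in each. Without replicate 4 of sham NMN, 4 of these 6 lists were lost and camera called 3, and leaving out another library cost 0 to 2 of the 6. Fry called 0 lists.

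The count of 0 came from edgeR's quasi-likelihood test, with 332 genes at unadjusted p under 0.05 against 735.8 expected. That fit shares 1 estimate of the spread over the 4 groups, so 332 does not show that the sham groups differ less than chance allows. Fitted on the 2 sham groups alone, 620 genes were at unadjusted p under 0.05 and 0 were called. With library weights in limma-voom 1584 were at that p. DESeq2 and limma-voom called 0, limma-voom with library weights 2, limma-trend on FPKM 0 with either pseudocount and 3 over all genes. With the split as a term 0 genes were called, and 2 within the first part. The second part held 1 sham NMN library. The inflammatory, doxorubicin target, mesothelial, Schwann and lung lists changed direction with the scaling.

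The interaction asked whether the doxorubicin effect differed between NMN and vehicle mice. It did for many of the genes already named: the doxorubicin effect was more positive with NMN for Myh6 (log2 fold 2.56, SE 0.35), Atp2a2 (log2 fold 0.70, SE 0.18), Hrc (log2 fold 1.37, SE 0.14) and Sirt3 (log2 fold 1.04, SE 0.27), and more negative for Hmox1 (log2 fold -5.82, SE 0.88), Cdkn1a (log2 fold -2.27, SE 0.47), Cat (log2 fold -1.52, SE 0.18) and Gabarapl1 (log2 fold -1.89, SE 0.18), with 4 libraries in each of the 4 groups. Adjusted p for these ran from 3.9e-05 for Gabarapl1 to 0.0151 for Sirt3 (edgeR quasi-likelihood, Benjamini-Hochberg). Others among the smallest p were Mmab, which activates vitamin B12 (log2 fold 1.44, SE 0.13), Gpt, an alanine aminotransferase (log2 fold 2.20, SE 0.23), Mdga1 (log2 fold 4.27, SE 0.45), the annexin Anxa7 (log2 fold -1.31, SE 0.11) and the vault protein Mvp (log2 fold -1.40, SE 0.16). Myh7 (log2 fold -1.48, SE 1.14), Nampt (log2 fold -0.33, SE 0.24) and Mdm2 (log2 fold 0.00, SE 0.11) did not pass. The files place Mmab (ENSMUSG00000029575.17) on chromosome 5 from 114431034 to 114444060 and Anxa7 (ENSMUSG00000021814.17) on chromosome 14 from 20455260 to 20480133.

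In the calcium-handling list, 8 of 14 were more positive, 0 more negative and 6 did not pass (10 and 0 adjusted over the list alone), and of the ion channel genes 7 of 17 were more positive, 0 more negative and 10 did not pass (11 and 0 adjusted over the list alone). Antioxidant and NRF2 targets gave 1 more positive, 18 more negative and 10 not passing of 29 (2 and 19 adjusted over the list alone). For the ribosomal protein list, 0 of 30 were more positive, 11 more negative and 19 did not pass (0 and 16 adjusted over the list alone). MHC class II genes gave 4 more positive, 0 more negative and 3 not passing of 7 (7 and 0 adjusted over the list alone), glucocorticoid-responsive genes 0 more positive, 8 more negative and 7 not passing of 15 (0 and 9 adjusted over the list alone), and p53 targets 1 more positive, 6 more negative and 15 not passing of 22 (1 and 6 adjusted over the list alone). By camera, all of these lists passed (adjusted p = 8.1e-08 to 0.00499), and adjusted p = 0.230 to 0.348 with an estimated correlation, where none passed. Camera called 22 lists, 12 up and 10 down, and none with an estimated correlation (lowest adjusted p = 0.230). The NAD, platelet and mesothelial lists changed direction with the scaling.

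Over all genes the interaction called 2654, 1359 more positive and 1295 more negative (edgeR quasi-likelihood, Benjamini-Hochberg). The count was 3491 with the split as a term and 1382 within the first part. The second part held 1 library of each NMN group. Leaving out a single library gave 1673 (replicate 3 of doxorubicin NMN), 1703 (replicate 2 of doxorubicin NMN), 1713 (replicate 3 of sham NMN), 1757 and 1760 (replicates 3 and 4 of doxorubicin vehicle) and 4114 (replicate 2 of doxorubicin vehicle). With the split as a term and without replicate 3 of doxorubicin NMN it was 2575. On log2(FPKM + 1), limma-trend called 949 more positive and 1418 more negative (40.1% positive), and over all genes above 0, 472 and 810 (36.8%). Upper-quartile scaling moved the balance the other way, to 1597 more positive and 1063 more negative (60.0%).

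**Figure D3:**
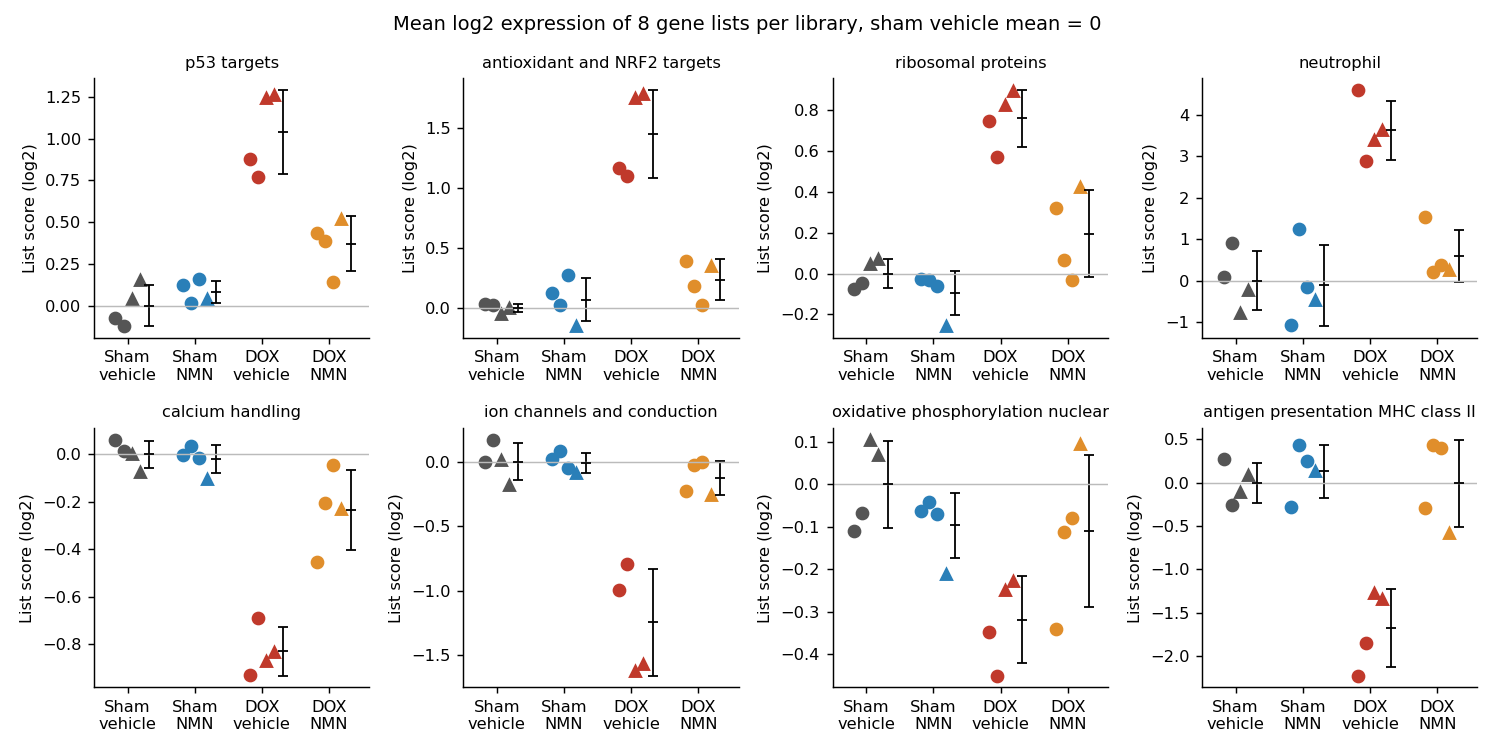
Mean log2 CPM of the genes of 8 fixed lists in each library, relative to the sham vehicle mean (vertical axis, log2), with circles for the first part of the split, triangles for the second, and mean ± SD per group. Calcium handling and MHC class II genes lie lower in doxorubicin vehicle than in doxorubicin NMN, and p53, antioxidant, ribosomal and neutrophil genes higher.

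**Figure D4:**
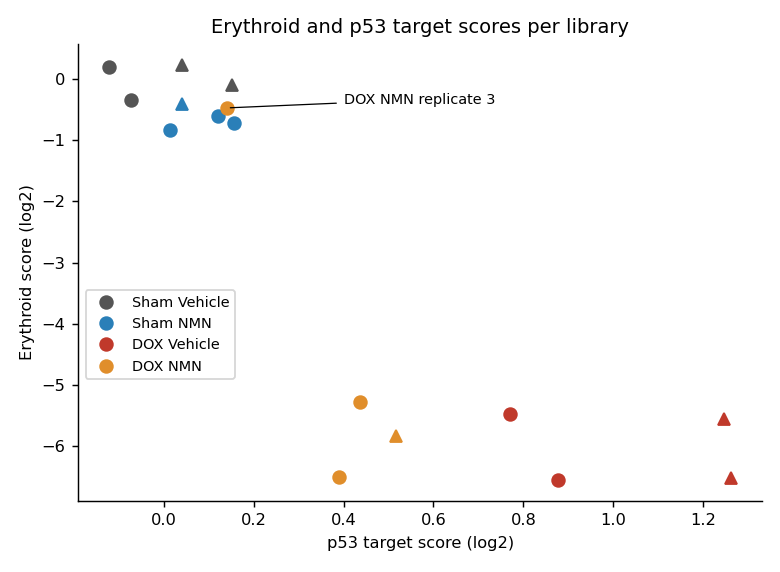
Erythroid list score (vertical axis, log2) against p53 target score (horizontal axis, log2) for the 16 libraries, relative to the sham vehicle mean, with circles for the first part of the split and triangles for the second. Replicate 3 of doxorubicin NMN, with a p53 target score of 0.14, lies among the sham libraries, and the other doxorubicin libraries have erythroid scores at or below -5.28.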

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

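The tests for a missing effective dose or wrong label and for GC content were written beforehand, and the tests of a swap, retained blood, harvest time, the split, replicate 3 alone, exposure and dose, and the counts over other splits of the samples were chosen only after the results were seen.

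Replicate 3 of doxorubicin NMN lay near the sham libraries, with Hbb-bs at 174 CPM where the other 7 doxorubicin libraries had 38 counts or fewer. A swap with a sham library is argued against, since 0 sham libraries had lost their erythroid genes, and so is retained blood as the whole cause, since its p53 target score was 0.14, within the sham range, against 0.39 to 0.52 in the other 3 doxorubicin NMN libraries. A candidate explanation is a doxorubicin dose that did not take effect, or a single wrong label. It lay outside the sham range in 10 of 49 lists, where sham libraries lay outside the range of the other shams in 5 to 20 and doxorubicin vehicle in 38 to 41. This test separates poorly, because replicate 2 of doxorubicin NMN gave 14 although its erythroid genes were lost. It also measures the same nearness to the sham libraries for which replicate 3 was picked, so it adds no separate support.

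The 6 libraries of the second part come from all 4 groups, and GC content is argued against as the whole cause, since of 1221 genes called between the parts 1091 stayed called after its trend was removed (limma, Benjamini-Hochberg), and the gap in Scand1, Cox11 and Mrps34 went from 2.08 to 1.92. The group differences do not come from the split alone, with 5397 genes called between doxorubicin NMN and doxorubicin vehicle when it was a term. A different time of harvest may explain it, because Arntl relative to Per2, Per3 and Dbp, clock genes of opposite phase, was higher in the second part by 7.40 in sham vehicle, 6.53 in sham NMN, 2.1 in doxorubicin vehicle and 2.72 in doxorubicin NMN (SD 0.90 within groups and parts). In the doxorubicin groups this was less clear. In doxorubicin vehicle Arntl was at 8.45 and 8.84 CPM in the first part and 30.4 and 30.7 in the second. Per2 stayed at 44.5 and 36.9 CPM and at 45.1 and 37.7. Replicate 4 of doxorubicin NMN, of the second part, had -1.60, below replicates 1 and 2 of doxorubicin vehicle, of the first (-1.34 and -1.08). The mean of the whole clock list was tried first and decides nothing, since its members go both ways. A library or batch difference stays open too, since the 48 genes over 65% GC had a mean deviation of -0.31 to -0.66 in these 6 libraries and of 0.0866 to 0.55 in the other 10 except replicate 2 of doxorubicin vehicle (-0.0731).

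The doxorubicin effect differed between NMN and vehicle mice by an interaction test, in 2654 genes and in 22 lists by camera at its preset correlation (0 lists with an estimated correlation). It was 2.56 for Myh6, 0.70 for Atp2a2, -2.27 for Cdkn1a, -5.82 for Hmox1, 0.43 for Nmnat3, 0.52 for Parp1, -0.90 for Sirt1, 1.04 for Sirt3 and -4.32 for Pdk4 (adjusted p = 4.4e-04, 0.0138, 0.00661, 0.00127, 0.0423, 0.0223, 0.0304, 0.0151 and 0.0187, edgeR quasi-likelihood, Benjamini-Hochberg). Replicate 3 alone is argued against, since 3841 of 5306 genes stayed called between the doxorubicin groups without it, and so is a lack of exposure in the other 3 mice, whose highest erythroid score was -5.28 against a lowest sham of -0.84. A lower effective dose in those 3 cannot be told apart from an action of NMN, because their erythroid score exceeded that of doxorubicin vehicle by only 0.15 in genes close to 0 counts. The effect of NMN named by the design stays open.

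Calls for Nmnat3, Sirt1, Parp1 and Pdk4 in the interaction were lost under some settings. Nmnat3 lost its call under limma-trend on log2(FPKM + 1) (0.34) and without any 1 library (0.39 to 0.46) other than replicate 2 of sham vehicle, 4 of sham NMN, or 1 or 2 of doxorubicin vehicle. Sirt1 lost it without replicate 3 or 4 of sham vehicle, 2 or 3 of sham NMN, 3 or 4 of doxorubicin vehicle, or 2 or 3 of doxorubicin NMN (-0.90 to -0.74). Parp1 lost it under limma-trend (0.47) and without replicate 1 of sham NMN (0.48) or 3 of doxorubicin NMN (0.47), and Pdk4 under limma-voom (-3.48) and the replicate block (-4.18).

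Among 35 splits of the 8 libraries in each comparison, only the real one gave as many genes for doxorubicin vehicle against sham vehicle (7145, highest other 15) and for doxorubicin NMN against doxorubicin vehicle (5306, highest other 2661). A share of 1 in 35 is under 0.05 and is the smallest these splits can give, so chance is made unlikely but not excluded. For sham NMN against sham vehicle the real count of 0 (edgeR, with 332 at unadjusted p under 0.05, and 0 to 3 by the other tools) is reached by any split, so all 35 gave as many, and the highest other, 148, exchanged replicate 2 of sham vehicle and 4 of sham NMN, following the split of the 6 libraries. For doxorubicin NMN against sham NMN the same holds for all 35 (real 0, highest other 0, by edgeR with 1205 at unadjusted p under 0.05, and 0 to 10 by the other tools). These 2 counts of splits therefore decide nothing about chance. For the mean doxorubicin effect 1 of 100 splits, the real one, gave as many (5817, highest other 4514), which makes chance unlikely without excluding it. For the interaction 3 of 100 gave as many as 2654, a share under the limit of 0.05. The 2 others, 3679 (the highest) and 2727, moved labels among sham libraries only and put all 3 sham libraries of the second part into 1 group, so the structure of the libraries can give as many. With the split as a term the interaction had 3491.

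Single libraries stood apart from the other 3 of their group in 17 of 312 tests, where chance gives about 1 in 20, or 15.6. Replicate 4 of sham NMN, its only library in the second part, did so in the sarcomere (-0.21), oxidative phosphorylation (-0.21), autophagy (-0.078), clock (-0.23), ribosomal protein (-0.26) and fibroblast (0.37) lists. The others were replicate 1 of doxorubicin vehicle in mitochondrially encoded (-0.10) and atrial genes (-1.47), replicate 3 of doxorubicin NMN in mitochondrial biogenesis (0.00694), replicate 1 of doxorubicin NMN in neutrophil genes (1.53), and replicate 2 of sham vehicle in mesothelial genes (-0.48). Replicate 3 of sham vehicle stood apart in glycolysis (0.11), cardiomyocyte (0.0613) and T and NK cell genes (-0.55). In CPM, replicate 3 of sham NMN was high in Hmox1 (22.9) and Sirt1 (20.7), and replicate 2 of sham NMN in Top2a (3.05). These were not weighed further.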

How the results depend on the processing

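The settings of the split of the libraries were chosen only after the data were seen, and all other settings had been chosen before. Named genes that were called in the main fit were followed at an adjusted p under 0.05. The settings were other scalings, DESeq2, limma-voom, limma-trend on log2(FPKM + 1), the replicate block, the split term and each library left out. In doxorubicin vehicle against sham vehicle 167 of 182 kept their direction and call, in doxorubicin NMN against doxorubicin vehicle 154 of 186, and in the interaction 15 of 19. Many of them were named for large folds or small p in these same data. Over all genes, leaving out replicate 4 of doxorubicin vehicle lost 1227 of 7145 calls in the first comparison and 1616 of 5306 in the second. The 1 reversal was Alas2 in doxorubicin NMN against doxorubicin vehicle without replicate 3 of doxorubicin NMN (-0.29, against up to 3.75 without another library), the library that holds the erythroid counts. At 13.9 M to 16.4 M counts per library, changes in genes of few counts were limited by counting.

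Leaving out 1 library at a time, the count ran from 6062 to 7861 for doxorubicin vehicle against sham vehicle, 3760 to 6318 for doxorubicin NMN against doxorubicin vehicle, 0 to 0 for sham NMN against sham vehicle, 0 to 21 (without replicate 3 of doxorubicin NMN) for doxorubicin NMN against sham NMN, 1673 to 4114 for the interaction and 5073 to 6693 for the mean doxorubicin effect. Camera lists ran from 21 to 28, 18 to 26, 3 to 11, 10 to 14 and 19 to 30 in the first 5 of these. The score difference of doxorubicin NMN and doxorubicin vehicle ran from -1.29 to -0.88, and that of the sham groups from 0.03 to 0.10.

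By construction, a 2-fold limit lowered the counts to 2629, 1659, 1275 and 1020 for doxorubicin vehicle against sham vehicle, doxorubicin NMN against doxorubicin vehicle, the interaction and the mean effect, and an adjusted p under 0.01 to 2996, 851 and 3565 for the last 3. Fitting only the 2 groups gave 3294 for doxorubicin NMN against doxorubicin vehicle. The first part of the split, with 10 libraries, gave 4128, 3201, 1382 and 3473 for the same 4, and 2 for the sham groups. Why these 4 counts were lower than over all libraries was not tested. The second part gave 4850 for the interaction, 119 for the sham groups and 1911 for doxorubicin NMN against sham NMN, with lone libraries assumed to vary like the others. The signature score difference was -0.88 in the first part and -1.21 in the second, where the exact p could not pass, and -7.48e-05 between the sham groups in the second. Same-numbered libraries taken as a block gave -1.11 with an exact sign-flip p of 0.125, the smallest that 16 flips can give.

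Library weights in limma-voom raised the counts to 8503 for doxorubicin NMN against doxorubicin vehicle, 6975 for the interaction, 2 for the sham groups and 1 for doxorubicin NMN against sham NMN. limma-trend over all FPKM above 0 gave 1282 for the interaction, 3 for the sham groups and 4 for doxorubicin NMN against sham NMN, where DESeq2 gave 10, and 45 were called with the split as a term and replicate 3 of doxorubicin NMN left out. With an estimated correlation camera called 0 lists in each of the 5 comparisons, fry called 36 for doxorubicin vehicle against sham vehicle, 0 for the sham groups and 1 for doxorubicin NMN against sham NMN, and the split as a term gave 10 for the sham groups. The cause was not tested. Other settings stayed within 1.5 times the count.

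The replicate number as a block gave 7162, 5285, 0, 0, 2583 and 5833 genes in the order used for leaving out libraries. Of 24 pairings of groups by number, residual correlations ran from -0.12 to 0.40, 5 over 0.1, and 8 were the best match. Same numbers therefore did not mark matched libraries throughout. The numbers partly followed the split, since replicates 1 and 2 of every group lay in the first part and replicate 4 of every group in the second. Replicate 4 had 0.40 between the sham groups and 0.24 between the doxorubicin groups. Whether the numbers stand for pairs of samples is not settled by these values.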

Other observations

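All values in this part were computed as planned, except the values by library, which were chosen after the data were seen. Many connective tissue genes fell with doxorubicin. Of the extracellular matrix genes, 6 of 33 rose, 19 fell and 8 did not pass (6 and 19 adjusted over the list alone), and in the fibroblast list 1 of 12 rose, 7 fell and 4 did not pass (1 and 8 adjusted over the list alone). Lox, which crosslinks collagen (log2 fold 2.79, SE 0.29), rose, while the collagen-binding proteoglycan Lum (log2 fold -1.94, SE 0.31) and Islr (log2 fold -2.94, SE 0.44) fell. By camera, extracellular matrix and fibroblast genes passed (adjusted p = 0.0192 to 0.0225), and adjusted p = 0.383 to 0.569 with an estimated correlation, where none passed. In doxorubicin NMN against doxorubicin vehicle, matrix genes gave 14 higher, 7 lower and 12 not passing of 33 (14 and 9 adjusted over the list alone) and fibroblast genes 5 higher, 2 lower and 5 not passing of 12 (5 and 2 adjusted over the list alone), with Lox down (log2 fold -2.29, SE 0.28) and Islr up (log2 fold 2.35, SE 0.44). By camera neither passed (matrix adjusted p = 0.456, adjusted p = 0.894 with an estimated correlation). Single genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

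Genes of cell division and DNA repair were mixed. Of the cell cycle genes, 2 of 23 rose, 9 fell and 12 did not pass (2 and 9 adjusted over the list alone) with doxorubicin, with the kinetochore gene Cenpf (log2 fold -3.32, SE 0.55) and the nucleotide synthesis gene Rrm2 (log2 fold -1.47, SE 0.36) among those with the smallest p. Of the DNA repair genes, 5 of 21 rose, 3 fell and 13 did not pass (5 and 3 adjusted over the list alone), among them Xpc, a damage sensor (log2 fold 0.86, SE 0.10). In the doxorubicin target and transport list, 5 of 14 rose, 3 fell and 6 did not pass (5 and 3 adjusted over the list alone). Its Por, a reductase that can reduce doxorubicin (log2 fold 1.28, SE 0.17), and Cbr1, a carbonyl reductase (log2 fold -0.81, SE 0.19), had log2 fold -0.94, SE 0.16 and log2 fold 0.74, SE 0.19 in doxorubicin NMN against doxorubicin vehicle. Cell death genes gave 9 higher, 4 lower and 10 not passing of 23 (9 and 4 adjusted over the list alone), with the inflammatory caspase Casp4 (log2 fold 1.74, SE 0.34, and with NMN log2 fold -1.70, SE 0.34) and the inflammasome adaptor Pycard (log2 fold -1.94, SE 0.28, and with NMN log2 fold 1.38, SE 0.29). Heat shock genes gave 7 higher, 3 lower and 4 not passing of 14 (7 and 4 adjusted over the list alone), with the chaperone partner Bag3 at log2 fold 1.16, SE 0.20, and with NMN log2 fold -0.95, SE 0.20. By camera none of these lists passed (adjusted p = 0.0645 to 0.535), and adjusted p = 0.484 to 0.687 with an estimated correlation, where none passed.

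Some atrial and nerve genes fell with doxorubicin. Of the atrial genes, 1 of 9 rose, 4 fell and 4 did not pass (1 and 4 adjusted over the list alone), and of the Schwann and neuron genes 0 of 6 rose, 3 fell and 3 did not pass (0 and 4 adjusted over the list alone). By camera neither passed (adjusted p = 0.0543 to 0.330), and adjusted p = 0.383 to 0.687 with an estimated correlation, where none passed. The atrial score of replicate 3 of sham vehicle (-1.86) lay within the doxorubicin vehicle range of -2.32 to -1.47. Myl7, the atrial myosin light chain, was at 35.0 ± 28.8 CPM in sham vehicle, 0.282 ± 0.373 in doxorubicin vehicle and 28.9 ± 33.5 in doxorubicin NMN. Under limma-voom its calls were lost with doxorubicin (-6.61) and in doxorubicin NMN against doxorubicin vehicle (5.21). Kcnj3, an atrial potassium channel, fell (log2 fold -1.88, SE 0.31). How much atrium each sample held is not given in the sources used here. Dbh, which makes noradrenaline in sympathetic nerves, was at 4.78 ± 0.865, 0.155 ± 0.145 and 2.36 ± 0.858 CPM. Branched-chain amino acid genes gave 2 higher, 9 lower and 8 not passing of 19 (2 and 9 adjusted over the list alone) with doxorubicin and 8 higher, 0 lower and 11 not passing of 19 (10 and 0 adjusted over the list alone) with NMN added, with Mccc2 of leucine breakdown at log2 fold -0.82, SE 0.09, and with NMN log2 fold 0.71, SE 0.09. By camera this list did not pass with doxorubicin (adjusted p = 0.0543, and 0.546 with an estimated correlation). With NMN added it passed at the preset correlation (adjusted p = 0.00423) and not at the estimated one (adjusted p = 0.443). Its scores were -0.33 and -0.41 in replicates 1 and 2 of doxorubicin vehicle and -0.03 and -0.04 in replicates 3 and 4, within the sham range of -0.16 to 0.07.

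By library, Hbb-bs had 0, 6, 16 and 2 counts in doxorubicin vehicle, 38, 0, 2411 and 7 in doxorubicin NMN, and 2017 to 4334 in the sham libraries. Pdk4, which holds back glucose oxidation, was at 4397 and 5459 CPM in replicates 1 and 2 of doxorubicin vehicle and 321 and 359 CPM in replicates 3 and 4, where the sham libraries had 103 to 410.2 CPM.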
